A study of Mus musculus with 12 samples.

How the data were processed

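Chromatin was profiled by CUT&RUN, in which an antibody directs a nuclease to its target in permeabilised cells and the released fragments are sequenced, in C2C12 cells, a mouse myoblast line that fuses into multinucleated myotubes in low serum. Per the labels, the antibodies were against MBD2, a methyl-CpG binding protein and subunit of the NuRD chromatin remodelling complex, against H3K4me3, a histone mark of active promoters, and a control IgG. The 12 samples cover day 0 cells, day 1 cells, day 5 myotubes and day 5 reserve cells (the mononucleated cells left unfused), with 1 library per antibody and cell state. A brief trypsin treatment parted the day 5 fractions, per the series' design text, after differentiation in medium with 2% horse serum, per the labels' protocols. The titles abbreviate both day 5 fractions, which were read as the myotubes and reserve cells of the design text. The 4 IgG libraries were not analysed here.

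Reads were trimmed with Trim Galore, aligned to mm10 with Bowtie2 and filtered with SAMtools, and peaks were called with MACS2, per the submitters' processing notes. Their versions, the MACS2 settings and whether the IgG libraries served as control are not given in the sources used here. The design text also mentions later filtering of peaks by the authors' own programs, and whether the lists had passed it is not given in the sources used here. Each deposited list holds the peaks of 1 library, with a start counted from 1, an end, a length and a summit. The deposited pileup is a signal, the number of fragments over the summit, and was a whole number for every peak of every list. No scaling of the target library's own count was therefore seen, though a rounded pileup would look the same. The deposited fold enrichment is a ratio of that pileup to the local background, per the file headers. Of the deposited −log10 p-value and −log10 q-value columns, the names were damaged in the file headers, and they were identified by their place in the MACS2 layout and by a lowest value just above that of q = 0.05. These values are the authors' and serve here only to describe, rank or filter peaks within a list.

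Peaks on chromosomes 1 to 19, X and Y were used, 14948, 452, 288 and 111 MBD2 peaks and 19218, 17665, 26034 and 15920 H3K4me3 peaks in the order day 0, day 1, myotubes, reserve cells. Read totals are not given in the sources used here. In their place, the lowest local background of each list, from (pileup + 1)/fold − 1, gives the background coverage in fragments per base, which depends on depth and fragment length. It was 0.360, 0.286, 0.776 and 0.947 for MBD2 and between 1.08 and 1.47 for H3K4me3. Genes came from the GENCODE M21 basic annotation of mm10, 55413 genes of which 21938 are protein-coding. A gene carried a peak at its promoter when a peak overlapped by at least 1 bp the 1 kb either side of any of its transcript starts. It gained a peak when the first library had none and the second had at least 1, and lost it in the reverse case. H3K4me3 breadth is the number of bases covered by peaks within 5 kb of the gene's 5′ end. Because gains and losses are calls, a peak whose edge moves across the 1 kb limit counts as a change.

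With 1 library per group, no difference between libraries has a replicate check and no p-value is given. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Expected shares came from 100 random placements of peaks of the same widths on the same chromosomes. Gene lists were set against 10000 random lists of the same size, drawn among genes with the same state in the first library and matched on protein-coding or not, as a description of these libraries. Genes with MBD2 at day 0 were set against random lists matched on day 0 H3K4me3 state and on breadth in at most 10 bins. Bins with equal limits were merged, so genes without any H3K4me3 within 5 kb shared a bin. The 19 gene lists cover myogenic regulators, sarcomere and contraction, myoblast fusion, cell cycle, cell cycle exit, satellite and reserve cell genes, the Notch and Wnt pathways, DNA methylation readers with NuRD, imprinted, germline, adipocyte, bone and cartilage, neuronal, blood, liver, fibroblast and matrix, housekeeping and Hox genes. These lists, the main comparisons, 10 of the 13 alternative settings and the rule for named genes were chosen before the data were examined. That rule takes, per change of H3K4me3, up to 4 changed genes per list and direction and the 5 strongest gains and losses of any named gene. For MBD2 it takes the 10 strongest promoters per library, up to 4 genes per list, and the 10 strongest at day 0 among genes with MBD2 in all 4 libraries. It also takes the 3 strongest peaks per library and 9 genes named in advance (Mbd2, Myod1, Myog, Pax7, Myh3, Ckm, Ccnd1, Gapdh and Actb). Predicted genes were passed over, and any other gene named was chosen after its values were seen. The result of 1 gene that the rule takes is not reported here.

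The alternatives were the stronger 50% of each list, equal numbers of peaks per antibody (111 MBD2 and 15920 H3K4me3), promoter windows of 0.5 and 3 kb, protein-coding genes only, other definitions of overlap, merging of peaks within 1 kb, and all sequences. For the stronger 50% and for equal numbers, peaks were ranked by −log10 q, and elsewhere strength is fold enrichment. Settings added after seeing the data were a stricter call of change (no peak within 3 kb in the library without it), a limit of 10 fragments per base on local background, and equal numbers of H3K4me3 peaks with all MBD2 peaks kept. Random lists matched on state alone were also added. The calls were tested on simulated data: of 200 gains and 200 losses planted among 55413 genes, 200 and 200 were recovered with no other gene called. The planted peaks lay at starts far from other genes. This checks the code only and cannot show errors from shared promoters or moving edges. Of 200 AP-1 motifs planted in 1000 windows, 200 were found, and 29 further windows held the motif. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with random seed 20.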

Results

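MBD2 and H3K4me3 were mapped by CUT&RUN in C2C12 myoblasts at day 0, at day 1 of differentiation, and at day 5 in myotubes and in the reserve cells that had not fused, with 1 library for each. The lists held 14948 MBD2 peaks at day 0, 452 at day 1, 288 in myotubes and 111 in reserve cells, with median widths of 391, 284, 301 and 306 bp. The H3K4me3 lists held 19218, 17665, 26034 and 15920 peaks in the same order, with median widths of 1936, 1869, 1217 and 1729 bp. The background coverage behind these lists was 0.360, 0.286, 0.776 and 0.947 fragments per base for MBD2, and for H3K4me3 it ran from 1.47 at day 0 to 1.08 in reserve cells. Of the 111 MBD2 peaks of reserve cells, 69 lay where the local background was at most 10 fragments per base. No difference between libraries has a replicate check, and intervals cover counting error only.

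**Figure D1:**
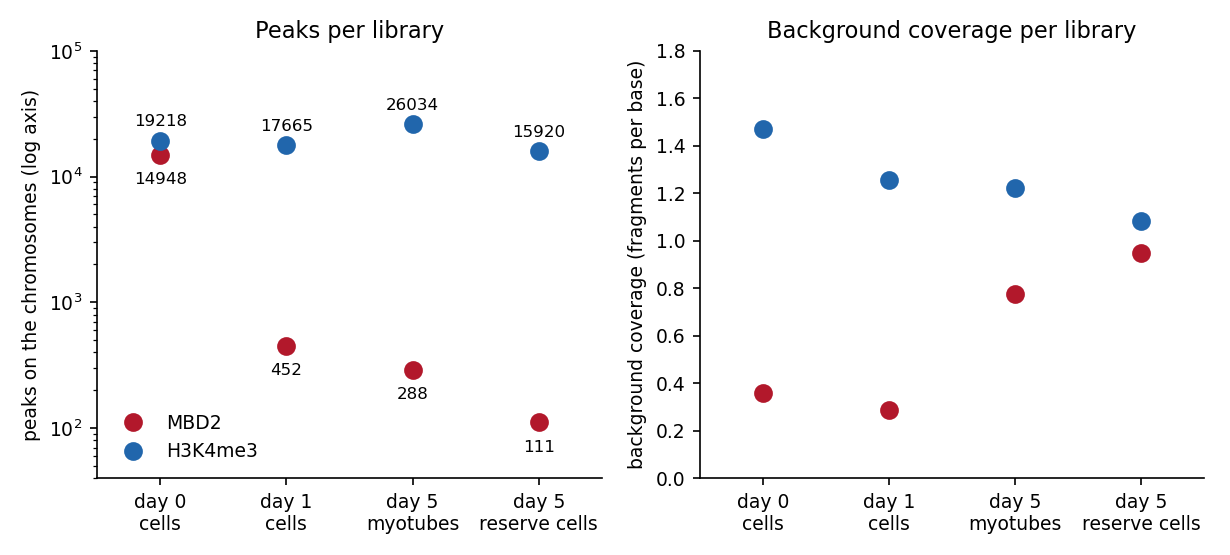
Peaks per library on a log axis and background coverage in fragments per base, for each antibody in the 4 cell states. MBD2 fell from 14948 peaks at day 0 to between 111 and 452 later, while its background coverage in both day 5 libraries, 0.776 and 0.947, was above the 0.360 of day 0.

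In day 0 myoblasts MBD2 lay at promoters and, more often, away from them. Its strongest peak (mm10 chromosome 1, 131526933 to 131528109, fold enrichment 116) covered the divergent starts of Srgap2, which encodes a regulator of actin and membrane shape, and Fam72a. Next among promoters came Rnf5 (chromosome 17, 34603338 to 34604531, fold 99.5), a ubiquitin ligase of the endoplasmic reticulum, and the shared upstream region of Mylpf and Tbc1d10b (chromosome 7, 127208742 to 127209493, fold 96.0). Mylpf encodes the regulatory light chain of fast skeletal myosin. Sp2 (93.4), Tomm40 (87.5), the import pore of mitochondria, Cnot3 (85.3), a subunit of the mRNA deadenylase, Sin3a (75.7), a histone deacetylase scaffold, and Cdca2 (69.8) followed. The peak with the 2nd highest fold (111) lay in an intergenic stretch of chromosome 8 (84381287 to 84382391), 1254 bp from the nearest annotated start.

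In the fixed gene lists MBD2 calls at day 0 were spread over most lists, and their counts were not set against random lists. Of all genes with H3K4me3 at day 0, 19.6% carried MBD2. MBD2 was called at 9 of 30 cell cycle genes, among them Mcm7, a subunit of the replicative helicase, Cdk1 (9.31), Top2a (7.35) and Aurka (6.37). It was called at 6 of 23 genes for DNA methylation readers and NuRD, led by Mbd3 (14.7) and Gatad2a (12.8), the former a relative of MBD2 found in separate forms of NuRD, the latter a NuRD subunit. Of 45 sarcomere genes 4 were called, Mylpf, Actn3 (16.9), Klhl41 (8.09) and Ldb3 (5.88), and of 12 myogenic regulators 3, among them Hes6 (5.15) and Six4 (5.02). The call fell on 4 of 21 satellite and reserve cell genes (Egr1 8.82, Foxo3 8.09, Vcam1 5.88 and Fos 5.15), on 4 of 20 Notch genes (Numb 15.1, Maml1 8.82) and on 4 of 27 Wnt genes (Fzd2 8.82, Fzd7 6.62). It also fell on 3 of 12 fusion genes (Myof 5.74), 3 of 11 cell cycle exit genes (Gadd45b 5.84), 4 of 28 imprinted genes (Inpp5f 7.97, and Peg10 with Sgce 5.02) and 3 of 14 bone and cartilage genes (Sox9 7.27). The remaining lists had 4 of 20 fibroblast genes (Lox 14.0, a collagen cross-linking enzyme), 5 of 20 housekeeping genes (Eef1a1 5.15), 5 of 28 Hox genes (Hoxc10 6.62), 1 of 12 adipocyte genes (Cebpa) and 1 of 14 liver genes (Apob 3.58). No germline, neuronal or blood gene carried an MBD2 promoter peak in any of the 4 libraries.

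Promoters held 19.8% of day 0 MBD2 peaks (95% interval 19.2 to 20.5), against 5.41% of randomly placed peaks, and 3527 genes had MBD2 at a start. By summit, 42.7% lay in introns and 36.5% between genes, against 41.6% and 50.8% of summits placed at random. Ranked by −log10 q, 63.1% of the 111 strongest day 0 peaks lay at promoters, and 20.5% of the stronger 50% of the list.

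Over differentiation MBD2 was called at far fewer promoters, and those peaks that were kept were mostly strong ones: 75% of the day 0 peaks still called at day 1 were among the strongest 20% of day 0. Of the 3527 genes with MBD2 at day 0, 3242 had no promoter peak at day 1, 3395 had none in myotubes and 3462 had none in reserve cells. Peaks covered 7.12 Mb at day 0 and 0.158, 0.121 and 0.0544 Mb later. A promoter peak in all 4 libraries was found at 28 genes, of which 26 carried H3K4me3 in all 4. Among them, Srgap2 and Fam72a had folds of 116, 56.7, 6.95 and 18.5 in the 4 libraries, Tomm40 87.5, 31.1, 9.11 and 8.22, and Tubb4b, a β-tubulin, 63.2, 31.1, 7.32 and 11.3. Sin3a had 75.7, 27.2, 4.17 and 8.22, and Rnf5, Cdca2, Kctd9, Rab40c and the mitochondrial carrier Slc25a25 were called in all 4 as well.

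Of the later MBD2 peaks, 90.3% at day 1, 53.1% in myotubes and 64.0% in reserve cells overlapped a day 0 peak. Genes with MBD2 later but not at day 0 were 18 of 303 at day 1, 54 of 186 in myotubes and 13 of 78 in reserve cells. In myotubes they included Acta1, skeletal muscle α-actin, with an MBD2 peak (fold 6.97; chromosome 8, 123895494 to 123895762) within 1 kb of a start that also gained H3K4me3, and Rbbp4 (4.29), a histone-binding subunit of NuRD. The leading myotube promoters were Slc25a25 (10.7), Cnot3 (9.65) and Kat7 (9.46), a histone acetyltransferase. In reserve cells they were Srgap2 with Fam72a (18.5), Tubb4b (11.3), Evi5l and Kdm4a (10.3 each), the last a histone demethylase, and Mylpf (9.25). Between the day 5 fractions, 146 genes had MBD2 in myotubes and none in reserve cells, and 38 the reverse. Of the list genes with MBD2 at day 0, Mylpf, Actn3 (13.2), Fzd2 (5.24), Inpp5f (4.62) and Aurka (4.49) kept a call at day 1, Actn3 (6.43), Dysf (5.89), a membrane repair protein, Mcm7 (5.63) and Fzd2 (4.79) in myotubes, and Mylpf in reserve cells. The lists of 452, 288 and 111 peaks are short, and with 111 peaks kept per library 24 promoter genes of day 0 were without MBD2 at day 1, 94 in myotubes and 71 in reserve cells. Under the same setting 47 genes, rather than 146, had MBD2 in myotubes and none in reserve cells.

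MBD2 coincided with H3K4me3 in all 4 cell states. At day 0, 36.3% of MBD2 peaks (35.5 to 37.0) overlapped an H3K4me3 peak, against 2.07% of random placements, and the share was 82.9% for promoter peaks and 24.7% for the others. It was 61.3% (56.6 to 65.8) at day 1, 72.2% (66.7 to 77.3) in myotubes and 53.2% (43.4 to 62.7) in reserve cells, against 1.73%, 2.36% and 1.40% at random. When placements were drawn among promoter windows alone the random shares were 31.5%, 29.8%, 31.1% and 29.0%. The day 0 share of all MBD2 peaks was 1.15 times that value, but most of those peaks lay away from promoters. The closer comparison is with promoter MBD2 peaks, of which 82.9%, 87.4%, 88.5% and 66.7% overlapped H3K4me3 in the 4 libraries. The share moved with the peaks kept: it was 59.5% for the 111 strongest peaks of day 0, and 18.0% at day 0 and 25.5% in reserve cells with the stronger 50% of each list. Both settings rank by −log10 q, which can put peaks of low fold at very high background first. In reserve cells the highest pileup had −log10 q 9334 at fold 2.55, against 37.7 for the peak of highest fold, 18.5. Genes with MBD2 at day 0 carried H3K4me3 in 87.9% of cases (86.8 to 89.0), and all annotated genes in 28.6%. The promoter share of MBD2 peaks was 49.3% at day 1 (44.6 to 54.0), 51.4% in myotubes (45.5 to 57.3) and 56.8% in reserve cells (47.0 to 66.1).

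**Figure D2:**
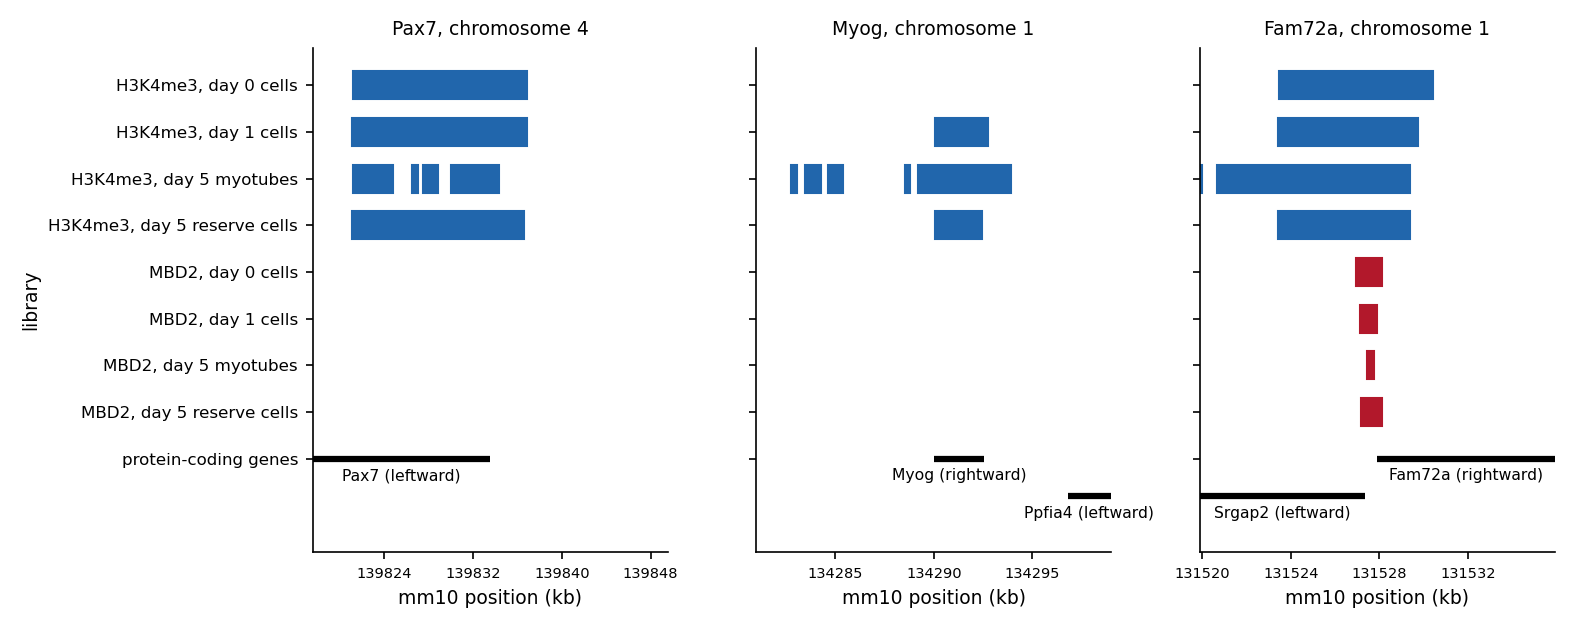
Deposited peaks around the starts of Pax7, Myog and Fam72a with Srgap2, in mm10 kilobases with 1 line per library and protein-coding genes below, each with its direction of transcription. H3K4me3 appears at Myog from day 1, MBD2 is called at the shared start of Fam72a and Srgap2 in all 4 libraries, and the 15720 bp day 0 peak over Pax7 is split into shorter peaks in myotubes.

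H3K4me3 was called at promoters of 15830 genes at day 0, 15608 at day 1, 16192 in myotubes and 15063 in reserve cells, 14624 of them in all 4. Mbd2 itself was marked throughout, with peaks of 3650, 3277, 2858 and 2982 bp (chromosome 18, 70567764 to 70571413 at day 0). Myod1, the myoblast determination factor, was marked in all 4 with peaks of 4508, 3846, 5282 and 3943 bp, as were Gapdh and Actb. Pax7, the satellite cell factor, lay under a peak of 15720 bp at day 0 (chromosome 4, 139821148 to 139836867), 15768 bp at day 1 and 15513 bp in reserve cells, and under 4326 bp at its start in myotubes, where other, shorter peaks covered part of the rest. Ccnd1, cyclin D1, had 8282, 5988, 2114 and 2978 bp. Of H3K4me3 peaks, 64.8%, 70.0%, 50.4% and 75.1% lay at promoters, against 8.74%, 8.59%, 7.88% and 8.29% of random placements. With the 15920 strongest peaks of each library the shares were 74.7%, 75.5% and 74.1% in the libraries other than reserve cells.

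By day 1, H3K4me3 had appeared at promoters of the contractile apparatus. Of 45 sarcomere and contraction genes 8 were marked at day 0, among them Des, Ttn, Ryr1, Tnnc1, Mylpf and Actn3, and 33 at day 1, with 25 of the 37 unmarked genes gaining a peak. The strongest new ones were at the troponins Tnnt1 (fold 22.2) and Tnnt2 (18.2), at Atp2a1 (16.0), the calcium pump of the sarcoplasmic reticulum, and at Klhl41 (13.3), which stabilises thin filaments. Myog, the regulator of terminal differentiation, gained a peak of 2673 bp (chromosome 1, 134290060 to 134292732, fold 11.1), and the fusion proteins Mymk (18.9) and Mymx (10.6) gained peaks too, Mymx beside 2160 bp already within 5 kb at day 0. No random list gained more than 5 genes where the sarcomere list gained 25, and 0.39% of random lists gained as many as the 2 of 6 fusion genes. With no peak allowed within 3 kb at day 0, 23 sarcomere and 1 of the fusion genes gained.

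The other day 1 gains in the lists were at Dcn (fold 18.2), a matrix proteoglycan, Prdm16 (4.88) and Tal1 (3.55), and the losses at Sox6, Slc17a7, Postn and Hoxb5. Over all genes 273 gained and 495 lost a promoter peak, and 333 and 345 with equal numbers of peaks. Of the strongest single gains, Tnnt1 and Gpr20 (26.1) had no H3K4me3 within 5 kb at day 0. Mir3058, Mir503 and Mir335 already had 3694, 2667 and 2528 bp there. The strongest losses, at Rap2b, Zscan25, Gpsm3, Mir6930 and Igflr1, had 4050, 2309, 6125, 3695 and 2707 bp at day 0 and 3933, 1772, 5088, 3109 and 2539 bp at day 1. At such genes the edge of a nearby peak may have moved across the promoter limit, which these lengths do not show. The new sarcomere peaks were not among the stronger 50% of the day 1 list, where 0 of 40 genes gained, and 1077 genes lost a peak under that setting. Of the myogenic regulators it left 66.7% marked at day 0 and 58.3% at day 1.

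**Figure D3:**
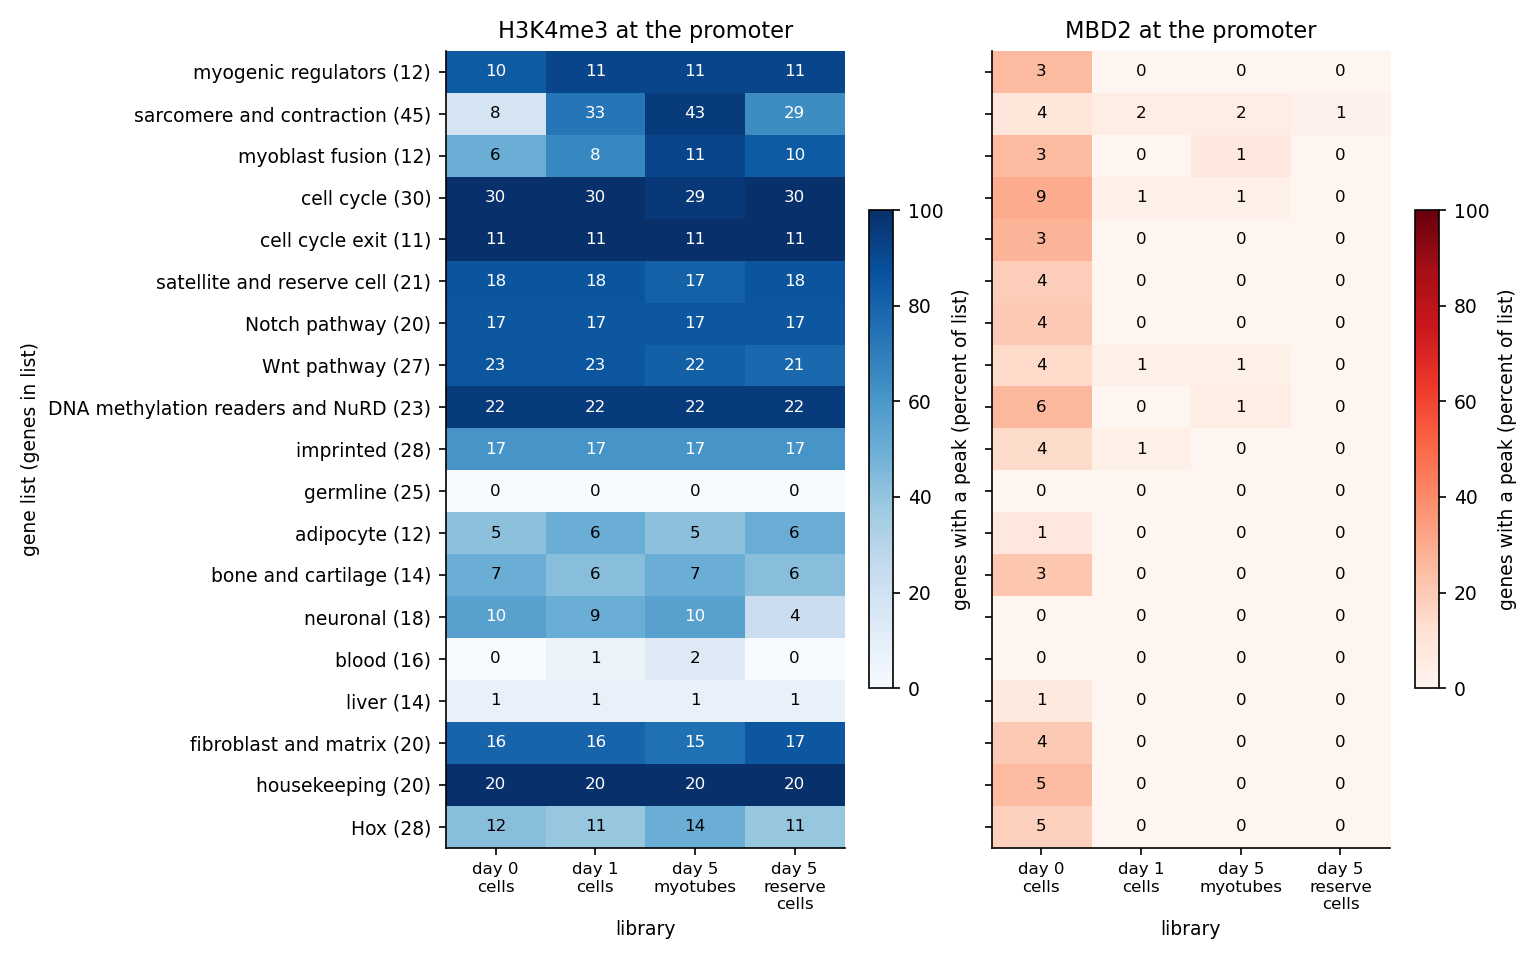
Number of genes of each fixed list (list size in brackets) with a promoter peak in each library, coloured by percent of the list, for H3K4me3 and MBD2. Sarcomere genes with H3K4me3 number 8, 33, 43 and 29 from day 0 to reserve cells, while cell cycle and housekeeping genes stay between 29 and 30 and at 20.

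In myotubes nearly the whole contractile list was marked. H3K4me3 was gained by 35 of the 37 sarcomere genes without it at day 0, leaving Myh2 and Myoz1 unmarked, and the peaks were broad: 9191 bp at Tnnt1 (fold 59.8), 6868 bp at Trim63 (56.7), a ubiquitin ligase of muscle protein turnover, 7194 bp at Klhl41 (55.6) and 5001 bp at Ckm (54.0), muscle creatine kinase. Myh3, embryonic myosin, went from none through 1249 bp at day 1 to 10192 bp, and Myog to 4706 bp (fold 45.4). Among the 6 unmarked fusion genes 5 gained a peak, Mymx (55.8), Mymk (31.4), Cav3 (30.7), Tmem182 (28.2) and Adgrb1 (3.92). Random lists of the same size gained at most 9 sarcomere and 4 fusion genes.

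The strongest gains of any named gene in myotubes were Ip6k3 (75.6), an inositol phosphate kinase, Mir6917 (65.7), Myom3 (63.4), an M-band protein of the sarcomere, Mir3058 (62.5) and Hfe2 (62.1), the bone morphogenetic protein co-receptor hemojuvelin. Among losses, Col6a3, a collagen VI chain, fell from 5598 to 355 bp within 5 kb, while Tslp had 3026 bp at day 0 and 3086 bp in myotubes within 5 kb, and Snord123, Mir214 and Snord7 kept 3380, 3040 and 3713 bp. Ccnb2, cyclin B2, lost a peak of 2277 bp and Cd34, a surface protein of satellite cells, 1 of 1325 bp, so 29 of 30 cell cycle and 17 of 21 satellite cell genes stayed marked. Further list genes lost Syt1, Dkk3, Sox6, Postn and Hoxb5 and gained Alpl (4.50), Elavl3 (2.95), Tal1 (5.85), Cd68 (4.50), Hoxb13 (4.82), Hoxd9 (4.50) and Hoxc8 (3.15).

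Over all genes 1012 gained and 650 lost a promoter peak in myotubes. With equal numbers of peaks 616 gained, of them 34 sarcomere genes, and 849 lost, so that losses outnumbered gains, and in the stronger 50% of each list 2220 gained, of them 36 sarcomere genes, and 197 lost. The myotube list has a median fold of 9.55 against 29.0 at day 0 and holds more weak peaks, so single gains with a low fold, such as the blood and Hox genes, were not kept with equal numbers of peaks.

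**Figure D4:**
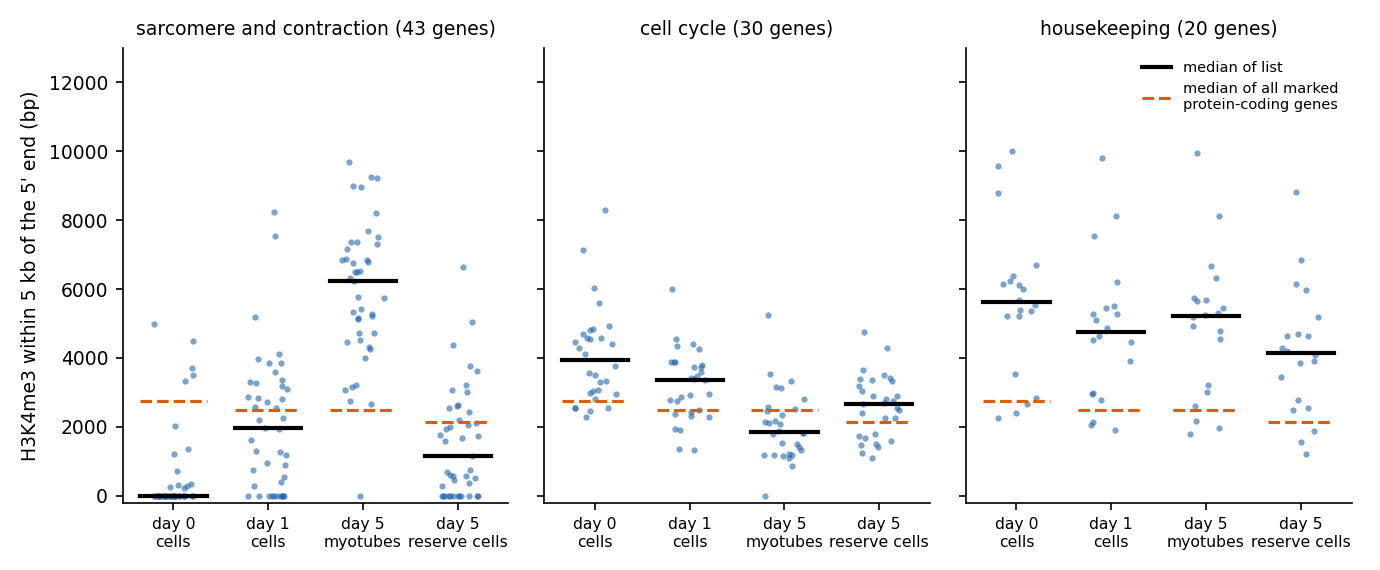
H3K4me3 in base pairs within 5 kb of the 5′ end for genes of 3 lists marked in any library, 1 point per gene, with the list's median and the median of all marked protein-coding genes. The sarcomere median is 0 bp at day 0 and 6234 bp in myotubes, and the cell cycle median falls from 3932 to 1863 bp.

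H3K4me3 breadth differed between these lists as well. The values are medians that were neither set against random lists nor recomputed with equal numbers of peaks. The sarcomere median was 0, 1967, 6234 and 1149 bp at day 0, day 1, in myotubes and in reserve cells, beside 2746, 2486, 2481 and 2132 bp for all marked protein-coding genes. The cell cycle median was 3932, 3374.5, 1863 and 2678.5 bp, and the fibroblast and matrix median 5031, 4464, 2735 and 3674 bp. Housekeeping genes had 5611.5, 4757, 5228.5 and 4141.5 bp, and myogenic regulators 4776, 5166, 5620 and 3943 bp. Of single cell cycle genes, Cdk1 had 4587 bp at day 0, 2161 bp in myotubes and 3051 bp in reserve cells, and Top2a 3058, 1145 and 1683 bp.

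Reserve cells also carried H3K4me3 at contractile genes, with narrower peaks than myotubes. Of the 37 sarcomere genes unmarked at day 0, 21 had a peak, led by Tnnt1 (4367 bp, fold 29.9), Tnnt2 (13.7), Tnnt3 (9.12) and Trim63 (9.12), and 4 of 6 fusion genes, Mymx (14.1), Mymk (6.57), Cav3 (5.76) and Tmem182 (3.84). Random lists gained at most 5 and 2. Myog had a peak of 2364 bp (fold 7.08) and Ckm 529 bp (7.68), and Myh3 had none. The strongest other gains were at Camk1g (26.9), a calmodulin-dependent kinase, and at Ccn5 (20.7) and Prelp (19.6), both of the extracellular matrix, while Mypopos (74.0) had 3926 bp nearby at day 0 already.

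Losses in reserve cells included 6 of the 10 neuronal genes marked at day 0, the neurofilaments Nefl (fold 23.0 at day 0) and Nefm (18.7), Sox2 (8.65), Syt1 (7.05), Map2 and Slc17a7. No random list lost more than 4. These lists were not matched on breadth, and the neuronal median at day 0 was 1295 bp, against 2746 bp for all marked protein-coding genes. The Wnt ligand Wnt1 (10.9) and Dkk3 (3.64), Sox6 (8.01) and Hoxb5 (3.13) lost their peaks as well. Snora2b, the strongest single loss (82.7), went from 6333 to 239 bp, while Snord7, Rap2b, Snord1a and Zscan25 kept 3069, 3991, 2149 and 1334 bp. All genes of the cell cycle (30 of 30), cell cycle exit (11), housekeeping (20) and Notch (17 of 20) lists that were marked at day 0 stayed marked, as did 18 of 21 satellite cell genes, among them Cd34. Over all genes 206 gained and 973 lost a promoter peak. With equal numbers of peaks 333 gained and 612 lost, and 5 of 9 neuronal genes lost. In the stronger 50% of each list 2007 genes lost a peak, none of 40 sarcomere and 8 fusion genes gained one, and 14 of 30 cell cycle, 3 of 20 housekeeping and 1 of 14 Notch genes lost theirs. Of the myogenic regulators 66.7% were then marked at day 0 and 41.7% in reserve cells.

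Compared with myotubes, reserve cells lacked H3K4me3 at part of the contractile genes and carried it at a few others. Of the 43 sarcomere genes marked in myotubes 14 had no promoter peak in reserve cells, and no random list lost more than 9. They were led by Klhl41 and Lmod2 (fold 51.1), which kept 2626 and 2600 bp within 5 kb, and by Tcap (32.1) and Myoz2 (31.1), proteins of the Z-disc, which had 0 bp. Myosin genes made up 5 of the 14 (Myh1, Myh3, Myh4, Myh7 and Myh8). Reserve cells alone of the 2 carried peaks at Postn (17.3), a matrix protein, Dcn (4.32), Cd34 (9.32), Ccnb2 (5.55) and Prdm16 (5.57).

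Among the 5 strongest differences of any gene, Hectd2os (fold 61.2) had 5055 bp in myotubes and 0 bp in reserve cells. At Mir6917, Mir3058, Mir6930 and Hist1h1d, and in the other direction at Mir15b, Mir16-2, Snord123, Mir214 and Mir26b, H3K4me3 lay within 5 kb in both. Further list genes with a peak in myotubes alone were Adgrb1, Wnt1 (5.78), Alpl, Elavl3, Nefm (8.63), Nefl, Sox2 (7.20), Slc17a7 (5.81), Map2 (5.40), Tal1, Cd68, Hoxb13, Hoxd9 and Hoxc8. Over all genes 275 had a promoter peak in reserve cells alone and 1404 in myotubes alone. These counts followed the lengths of the lists: with equal numbers of peaks they were 606 and 652, with 13 of 42 sarcomere and 2 of 6 neuronal genes in myotubes alone, and in the stronger 50% of each list 37 and 3901.

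With all peaks and the 1 kb window, lists without a gain or loss in any comparison were cell cycle exit (11 genes marked throughout), Notch (17), DNA methylation readers and NuRD (22 of 23, all but Tet1), imprinted (17 of 28), housekeeping (20), germline (0 of 25) and liver (1 of 14). Counts from day 0 to reserve cells were 5, 6, 5 and 6 of 12 adipocyte, 7, 6, 7 and 6 of 14 bone and cartilage, 10, 9, 10 and 4 of 18 neuronal, 0, 1, 2 and 0 of 16 blood, 16, 16, 15 and 17 of 20 fibroblast, 23, 23, 22 and 21 of 27 Wnt and 12, 11, 14 and 11 of 28 Hox genes. Several of these counts depended on the peaks kept. In the stronger 50% of each list, 11 of 25 imprinted and 3 of 4 NuRD genes gained H3K4me3 in myotubes, and 10 of 14 and 6 of 22 had it there but not in reserve cells. With equal numbers of peaks, 6 of 22 Wnt and 3 of 7 bone and cartilage genes lost it in myotubes, 5 of 11 Wnt genes had it in reserve cells and not in myotubes, and no Hox gene changed. With no peak allowed within 3 kb, the losses of Sox6 and Postn at day 1 and in myotubes and of Slc17a7 at day 1 were not called. With 0.5 kb promoters 1 cell cycle exit gene gained and 1 Notch gene lost a peak in each change from day 0. Among protein-coding genes alone, 164, 508 and 132 gained and 231, 343 and 511 lost a promoter peak from day 0 to day 1, myotubes and reserve cells, and 159 and 703 had it in reserve cells or in myotubes alone.

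Over all annotated genes, those with MBD2 at day 0 gained H3K4me3 more often than matched unmarked genes. Of the 426 genes with MBD2 and no H3K4me3 at day 0, such as Klhl41, 5.16% gained it at day 1 (3.26 to 7.71), 15.3% in myotubes and 3.99% in reserve cells (2.34 to 6.31). Random lists matched on H3K4me3 state and breadth gained 0.791%, 2.90% and 0.565% on average, with a highest value of 6.81% in myotubes. Unmarked genes with 0 bp nearby shared 1 bin, so breadth was matched coarsely at most among them. Of the 3101 with both MBD2 and H3K4me3 at day 0, 2.23%, 1.84% and 4.19% lost it, against 2.33%, 3.13% and 4.61% at random, and no random list was as low as the 1.84% of myotubes. With equal numbers of H3K4me3 peaks and all MBD2 peaks, gains were 7.36%, 9.61% and 5.73% of 489 genes against 0.912%, 1.73% and 0.872%, and losses 1.55%, 3.19% and 2.57% of 3038 against 1.75%, 4.28% and 3.13%. Among 74 protein-coding genes the excess was not clear at day 1, where 4 gained it, 5.41% against 1.96% at random, and 587 of 10000 random lists gained as many. In myotubes 18 gained it, 24.3% (15.1 to 35.7) against 6.07%, and in reserve cells 5, 6.76% against 1.49%, while 0.551%, 0.551% and 1.23% of 2358 lost it, against 0.910%, 1.48% and 2.14%. Shares moved with the peaks kept: with the stronger 50% of each list 30.3% gained H3K4me3 in myotubes, and 6.64% at day 1 and 14.3% in reserve cells lost it. With 111 MBD2 peaks the gains were 38.1% at day 1, 0% in myotubes and 42.9% in reserve cells, of few genes.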

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

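The sarcomere test in this part was written for a gain already seen, before its outcome with equal numbers of peaks was known. The day 5 fractions moved in opposite directions from day 0 in 4 counts, differences between groups that were not tested since each rests on 1 library. The number of H3K4me3 peaks changed by 6816 in myotubes and by −3298 in reserve cells, and the number of genes with a promoter peak by 362 and −767. Fibroblast and matrix genes with promoter H3K4me3 changed by −1 in myotubes, where Postn was without its peak, and by 1 in reserve cells, where Dcn had gained it. Hox genes changed by 2 and −1. Those of the promoter genes and Hox genes did not hold for lists of equal length. The difference in peak number is removed there by construction, since every list then holds 15920 peaks. With equal numbers of H3K4me3 peaks, 616 genes gained and 849 lost a promoter peak in myotubes and 333 gained and 612 lost it in reserve cells, a net loss in both, and no Hox gene gained one in myotubes.

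MBD2 peaks outside the analysed chromosomes are data that no comparison used. Their median folds were 5.82, 1.88, 2.58 and 1.79 from day 0 to reserve cells, and whether they reflect MBD2 binding was not tested. There were 20 at day 0, 18 at day 1, 14 in myotubes and 24 in reserve cells, on the mitochondrial genome (2, 8, 0 and 0) and on unplaced sequences, of which JH584304 held 1, 4, 13 and 24.

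The gain of H3K4me3 at sarcomere genes in myotubes was weighed against the longer list of that library, which holds 26034 peaks at a median fold of 9.55. If weak extra peaks were the cause, few gains should remain with equal numbers of the strongest peaks, and 34 of 37 gained it, beside 35 with all peaks. A longer list is therefore excluded as the main cause. Cell state and the success of the H3K4me3 reaction in each single library cannot be told apart here. The 21 sarcomere gains in reserve cells could come from those cells or from myotubes left in the fraction, which these lists cannot separate.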

How the results depend on the processing

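No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out in turn. The planned use of the authors' gene annotation was not run, since the lists carry none. Over 13 settings, 254 values of 58 results were recomputed: 145 stayed within their limits, 109 moved (11 of them not main results) and 0 reversed. The limits of a count were a fixed fold change either way, and those of a share were its main interval. Single counts cannot change sign, however, and the balance of gains and losses from day 0 to myotubes did turn, from 1012 gained and 650 lost to 616 gained and 849 lost with equal numbers of peaks. Of these values none passed its limits with all sequences, with peaks merged within 1 kb, or with no peak allowed within 3 kb. Counts did change within those limits. With no peak allowed within 3 kb, 353, 493 and 748 genes lost H3K4me3 from day 0, rather than 495, 650 and 973. Reserve cell MBD2 peaks numbered 135 with all sequences, rather than 111. Changes within gene lists are not among these values, and some of those did move, as the report states. Depth could limit the weak peaks of each library, but both day 5 MBD2 lists, the shortest, have 2.15 and 2.63 times the background coverage of day 0. Except where fewer peaks or genes enter by construction, the cause was not tested. Values below run in the order day 0, day 1, myotubes, reserve cells, or day 1, myotubes, reserve cells for changes from day 0.

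With the stronger 50% of each list, peaks numbered 7474, 226, 144 and 55 for MBD2 and 9609, 8832, 13017 and 7960 for H3K4me3 by construction. H3K4me3 peaks lay at promoters in 95.4%, 96.6%, 85.2% and 97.4%, MBD2 peaks in 20.5% at day 0 and 64.2% at day 1, and MBD2 overlapped H3K4me3 in 18.0%, 50.9%, 52.8% and 25.5%. Genes without their day 0 MBD2 numbered 1706, 1830 and 1868, and those with MBD2 in myotubes but not reserve cells 77. H3K4me3 was gained by 2220 genes in myotubes and by 37 from myotubes to reserve cells, and lost by 1077, 197 and 2007, and by 3901 from myotubes to reserve cells. Of day 0 MBD2 genes 30.3% gained H3K4me3 in myotubes, and 6.64%, 0.989% and 14.3% lost it.

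With equal numbers of peaks, 616 genes gained H3K4me3 in myotubes, 333 in reserve cells and 606 from myotubes to reserve cells, while 612 lost it in reserve cells and 652 from myotubes to reserve cells. Day 0 MBD2 was missing later at 24, 94 and 71 genes, and myotube MBD2 in reserve cells at 47. H3K4me3 peaks lay at promoters in 74.7%, 75.5% and 74.1% (day 0, day 1, myotubes), MBD2 peaks in 63.1% and 76.6% (day 0, day 1), and MBD2 overlapped H3K4me3 in 59.5%, 69.4% and 56.8%. Of day 0 MBD2 genes 38.1%, 0% and 42.9% gained H3K4me3 and 1.15%, 3.45% and 2.30% lost it. With all MBD2 peaks kept, 9.61% gained it in myotubes and 1.55%, 3.19% and 2.57% lost it.

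With promoters of 0.5 kb the H3K4me3 shares were 63.5%, 68.6%, 48.8% and 73.8%, the day 0 MBD2 share 16.9%, and losses of day 0 MBD2 genes 1.73%, 1.35% and 3.23%. With 3 kb they were 69.5%, 74.8%, 58.0% and 80.1%, for MBD2 28.6% at day 0 and 54.6% at day 1, and losses 3.17% at day 1 and 5.35% in reserve cells. With protein-coding genes only, gains were 164, 508 and 132, and 159 from myotubes to reserve cells, and losses 231, 343, 511 and 703. Promoter shares were then 60.0%, 65.3%, 45.7% and 70.6% for H3K4me3 and 15.3%, 41.4% and 44.1% for MBD2 (day 0, day 1, myotubes), and of day 0 MBD2 genes 24.3% gained H3K4me3 in myotubes and 6.76% in reserve cells, and 0.551%, 0.551% and 1.23% lost it. The day 0 overlap of MBD2 with H3K4me3 was 31.5% when 50% of the MBD2 peak had to be covered and 31.8% by summit, and 69 reserve cell MBD2 peaks remained with local background of at most 10.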

Other observations

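Genes in the next 2 paragraphs were chosen after their values were seen. Among the 65 genes with MBD2 and no promoter H3K4me3 at day 0 that had H3K4me3 in myotubes were, besides Klhl41, 4 picked by hand here, which show no theme by themselves. Stac3, a protein of excitation-contraction coupling, had MBD2 of fold 4.41 at day 0 and H3K4me3 of fold 55.8 in myotubes. Mypn, a Z-disc protein, had 5.15 and then 20.2, Dusp13, a phosphatase gene, 4.47 and then 23.4 beside 2445 bp within 5 kb at day 0, and Lrrc30 10.3 and then 9.14. None of them had an MBD2 call in myotubes.

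Of the 28 genes with MBD2 in all 4 libraries, 4 more are given here without a test of any shared function. Tcf3, which encodes the E proteins that pair with MyoD, had folds of 16.2, 8.55, 6.63 and 7.71 from day 0 to reserve cells. The shared start of Cbx5, heterochromatin protein 1α, and Hnrnpa1 had 24.4, 8.36, 6.14 and 6.16, and the homeobox gene Irx3 12.5, 5.44, 4.26 and 7.10. Among genes with MBD2 in myotubes alone were Smad7 (5.63), an inhibitor of transforming growth factor β signalling, Sod2 (6.50), the mitochondrial superoxide dismutase, Pvalb (5.89), the calcium buffer of fast muscle, and Pfkfb3 (4.82), a regulator of glycolysis.

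In what follows, the day 5 depth test, the comparison at equal strength with its limit, the AP-1 and E-box controls, the split of kept peaks by AP-1 and, for the palindrome, the reference at summits and the use of the upper limit were chosen only after the result was seen. The other tests were written before. Of 7 motifs searched, AP-1, the E-box and the palindrome had a prediction.

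The fall in MBD2 peaks was weighed against depth and against a general lowering of enrichment. Lower depth at day 5 is argued against, since the lower of both background coverages was 2.15 times that of day 0. That coverage also depends on fragment length and read totals are not given, so lower depth is not excluded. By the same coverage, depth alone is argued against at day 1. There the pileup at the 100 strongest day 0 peaks fell to 0.255 of what the background ratio gives. The values in myotubes and reserve cells, for which no prediction was written, were 0.0591 and 0.0553. Only 25 of the 100 peaks were called in each, and uncalled peaks were set at the list's lowest pileup. A general lowering that leaves strong sites above the threshold could account for much of the fall, since 75% of the kept peaks were among the strongest 20%. Promoter peaks were kept at day 1 1.90 times as often as all peaks in the same bin of day 0 strength. Of the 205 kept promoter peaks, 130 lay in the strongest bin, which reaches a fold of 116. Strength was not equal within that bin, so the ratio cannot decide about an equal lowering at every site. A simulated equal lowering gave 1.09, at 1 setting that was not matched to the number of peaks kept. Cell state and the success of the MBD2 reaction in each single library cannot be told apart here.

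The day 0 MBD2 peaks away from promoters and H3K4me3 were weighed against dense CpG and transcription factor sites. Their CpG density was 1.53 times that of random placements, under the 2 times set for dense CpG as the only feature. The AP-1 motif, bound by Fos and Jun proteins, lay near 22.1% of 9008 summits against 3.24% at random, 6.82 times as often, and at 4.13% of points 1 kb away and 4.16% of H3K4me3 peaks away from promoters without MBD2. It was not particular to them: the other day 0 MBD2 peaks held it at 16.0% (away from promoters, with H3K4me3) and 7.27% (promoters). H3K4me3 promoter peaks without MBD2 held it at 1.68%. Of the peaks away from promoters and H3K4me3, at any local background, 9 of 1990 with AP-1 and 104 of 7032 without it were kept at day 1. These were 0.192 and 0.660 times the number expected from all day 0 peaks of similar strength, promoter peaks included. Sites with AP-1 factors remain a possible source, as does untargeted cutting at open chromatin, since the IgG libraries were not analysed here, and the peaks were not tested against a difference between the cell states.

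A shared palindrome, TCTCGCGAGA, was tested as a hypothesis for the promoters that kept MBD2, and it is excluded as a sequence they share near the summit. It lay there in 0 of 201 such peaks, a ratio of 0 with an upper limit of 1.82% for the share, and in 2 of all 2959 day 0 MBD2 promoter peaks. H3K4me3 promoters without MBD2 held it at 62 of 9831 starts (0.631%), and at 1 of 9831 summits, too few to compare. The E-box lay at 13.4% of the distal peaks, 2.02 times its share at random placements, but at 8.53% of points 1 kb away and 13.5% of H3K4me3 peaks away from promoters without MBD2. Other motif ratios over random placements were 2.29 for RUNX, 3.43 for CTCF, 0.889 for ETS and 1.01 for CACGTG. Of the 9008 distal peaks, 1.82% overlapped H3K4me3 at day 1, 9.89% in myotubes and 0.533% in reserve cells, against 0.0809%, 0.579% and 0.0340% of random placements. The highest MBD2 pileups, 27634, 31647, 61010 and 65495 fragments, lay at the same place on chromosome 2. Their folds over the local background were only 1.59, 2.31, 2.56 and 2.55, so they are not read as MBD2 binding.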
